A study of Mus musculus with 16 samples.

How the data were processed

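Bulk RNA sequencing was carried out on lungs of C57BL/6 mice bearing HKP1 tumours, in 16 libraries of 6 groups (a radiation dose of 0, 4 or 8 Gy, with IgG or anti-PD-1). Per the labels' protocols, lungs were ground, RNA was extracted with a column kit, and libraries were made from 1 µg of total RNA with the TruSeq RNA kit. Per the submitters' processing notes, the tools were STAR, an aligner, and Partek, an analysis suite, on the mouse build mm10. Their versions, the annotation, the counting setting and the use of strand are not given in the sources used here. Each library's group and replicate number came from its title, and each column was matched to 1 library by the name in that title.

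The deposited values cover 30095 genes with chromosome, start and stop and 1 column of CPM (reads scaled to the library's total) per library, to which the authors had added 1e-04, the value of genes with no reads. The CPM of the listed genes summed to between 866773 and 915009 per library. In each column the commonest low value gave the worth of 1 read, which ran from 0.0155 CPM in the deepest library to 0.0418 CPM in the shallowest. Of the values under 100 reads, 60.5 to 63.7% were whole reads within a tolerance of 0.02, so the reads could not be recovered and no count model was used. A floor of 3 reads corresponds to at most 0.125 CPM in the shallowest library, and it covers counting error only. The design fixed before the data were examined gave a different test for each unit the table could hold, and the CPM unit decided that limma was used.

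Genes were matched to GENCODE M21 on mm10: 29369 names and 29829 positions were found there, and the deposited stop lies 1 base past the gene's end. A spreadsheet program had turned 25 symbols into dates, and 23 were restored from their coordinates. Without strand, reads of genes that overlap on opposite strands cannot be told apart. Among the genes named here, the annotated spans of Cd274, Acta1, Rbpjl with Matn4, Dnah3, Tgtp1, Mfap4 and D330041H03Rik with Abca3 overlap that of another gene. Members of gene families with near-identical copies, such as Ccl21a, Ifit3, Tgtp1, the haemoglobins and the immunoglobulins, may share reads.

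The values were tested as log2(CPM + 0.5) with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes) and version 1.17.8 of data.table, over the 17546 genes at 1 CPM or more in at least 2 libraries. All 16 libraries entered 1 fit of the 6 group means with no replicate block, and dose comparisons over both antibodies average the difference within each. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. Fold changes are on the log2(CPM + 0.5) scale, which understates the change of low genes, and are given ± SE. CPM levels are given ± SD. The gene lists, 35 with 547 symbols of which 545 were present, were fixed before the data were examined and tested with camera at its preset correlation of 0.01. They were tested again with the correlation estimated from the residuals, under which the calls of 5 of 161 list results held: the p53 targets at 8 and 4 Gy against 0 Gy and at 8 Gy with IgG, and the immunosuppressive myeloid genes at 8 Gy against 0 Gy and at 8 Gy with IgG. A list's count "adjusted over the list alone" applies Benjamini-Hochberg to its members only.

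Genes were named by a rule fixed before the data were examined. For the 4 comparisons over both antibodies or all doses, it takes genes past the threshold with a mean log2 value of at least 1, the same sign in each arm (or at each dose) and an informative symbol. Of these it takes the 10 largest rises and falls and the 5 with the lowest p in each direction. For the others it takes up to 5 with the lowest p in each direction. It adds up to 4 members of each list with the lowest p, and always Cdkn1a, Mki67, Scgb1a1, Pdcd1, Cd274, Ifng and Trp53. The text names those that fit its sentences.

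The procedure was tested on simulated Gaussian values, drawn for each gene independently with its real mean and SD. In them 200 of 17546 genes were changed, chosen among those with a mean log2 value above 1. For 8 Gy against 0 Gy it recovered 42% of genes changed 1.5-fold, 80% of those changed 2-fold, 98% at 4-fold and 96% at 8-fold, with 5 false calls. For 4 Gy against 0 Gy with IgG it recovered 14, 52, 90 and 100% at the same sizes, and for anti-PD-1 against IgG at 8 Gy 12, 62, 90 and 100%. Camera called the list that was shifted and 0 others. Because the simulated genes vary independently, the few false calls do not show how the tests behave on genes that vary together.

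The alternatives planned were quantile normalization, no filter on low values, pseudocounts of 0.1 and 1, a replicate block, a fit of the compared groups only, an additive model of dose and antibody, an estimated correlation in camera, other gene subsets for the correlation of arms, and leaving out each replicate in turn. Further alternatives were added after seeing the data. They included a fit without anti-PD-1 4 Gy replicates 2 and 3 (the 2 outlying libraries, set apart as shallow and lying farthest out on the first principal component). The others were library weights, totals without mitochondrial and haemoglobin genes, GC-corrected values, library medians set equal, and single-term interactions at each dose. Library weights were estimated gene by gene because the REML estimate did not converge. The GC correction was a loess fit of span 0.3 over the 17309 genes with a GC value. The rules that weigh the explanations for the muscle genes and for correlations across libraries were tightened after their values were seen, so that they exclude or accept less. Every column of values in the table belonged to a library and was used.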

Results

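Messenger RNA was measured by RNA sequencing in tumour-bearing lungs of C57BL/6 mice. The tumours grew from HKP1, a mouse lung adenocarcinoma line, so each library holds RNA of tumour cells, resident lung cells and infiltrating immune cells together. The lungs had received a radiation dose of 0, 4 or 8 Gy, together with a control antibody (IgG) or an antibody against PD-1, the checkpoint receptor that restrains T cells. They were taken 24 to 48 hours after irradiation, and each library was made from a pool of 3 to 4 mice. The 16 libraries comprised 3 with IgG at 0 Gy, 2 with IgG at 4 Gy and 3 with IgG at 8 Gy, and 2 with anti-PD-1 at 0 Gy, 3 with anti-PD-1 at 4 Gy and 3 with anti-PD-1 at 8 Gy. The submitters' title names the question: how radiation and checkpoint blockade act together in lung tumours, with a focus on the airway's secretory club cells, which are marked by Scgb1a1.

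The worth of 1 read, which falls as depth rises, ran from 0.0155 to 0.0418 CPM. Replicates 2 and 3 of the anti-PD-1 4 Gy group, below called the 2 outlying libraries, lay farthest from the others on the first principal component, at -81.5 and -98.3, where the other 14 libraries lay between -46.8 and 51.9. In these 2, 1 read was worth 0.0418 and 0.0319 CPM, against 0.0334 CPM in anti-PD-1 0 Gy replicate 1, so depth alone does not set replicate 3 apart. They had 6086 and 5315 genes with no reads, against 2273 to 3851 in the other libraries. Mitochondrial transcripts took 1.01 to 3.73% of the CPM in unirradiated libraries, 4.14 to 6.54% at 4 Gy and 1.69 to 8.23% at 8 Gy. Haemoglobin transcripts took 0.216 to 3.29% over all libraries. The labels name no preparation batch and do not say whether the pools of a group came from separate mice, so p-values measure the spread between these pools. The running sheet numbers of the libraries were 13 to 17 at 0 Gy and 26 to 36 after irradiation. If these mark separate preparations, preparation and irradiation cannot be told apart. The 4 and 8 Gy libraries lay within 1 run of numbers, but as successive blocks, 26 to 30 and 31 to 36. Within each dose the IgG libraries came first, so an effect of order could not be told apart from dose or antibody either.

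**Figure D1:**
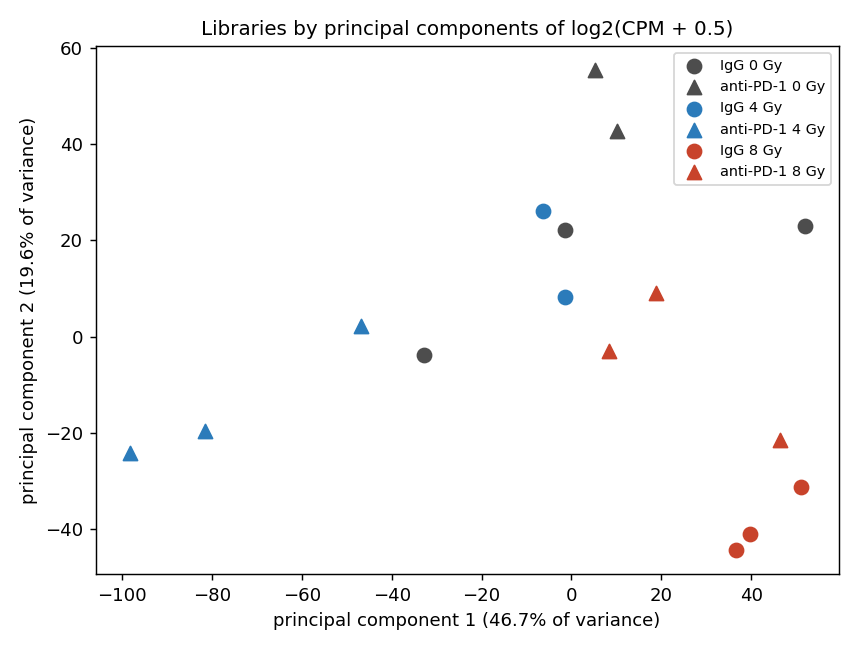
Principal components of log2(CPM + 0.5), with component 1 (46.7% of the variance) on the x axis and component 2 (19.6%) on the y axis and 1 point per library. Anti-PD-1 4 Gy replicates 2 and 3 sit at the far left, at -81.5 and -98.3 on component 1.

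Lungs that received 8 Gy were compared with unirradiated lungs over both antibodies, which asks what the higher dose did to the tissue (n = 6 and 5). A p53 target and large parts of the interferon response were higher at 8 Gy, together with part of the genes of monocytes and macrophages and of cytotoxic lymphocytes. Part of the markers of alveolar type 1 cells, ciliated cells and the connective-tissue matrix were lower. The lowest p of any rise belonged to Cdkn1a, which encodes the cell cycle inhibitor p21 (mm10, chromosome 17, 29090976 to 29100727, plus strand). It stood at 50.7 ± 9.22 CPM (SD, n = 5) at 0 Gy and 160 ± 33.1 CPM (n = 6) at 8 Gy, a log2 fold change of 1.63 ± 0.13 (SE, limma, adjusted p = 5.09e-05), and every 8 Gy library lay above every 0 Gy library. The largest rise was in Ccl24, a chemokine for eosinophils, by 2.75 ± 0.25 on the log2 scale (adjusted p = 7.84e-05). It was followed by Acod1, the macrophage enzyme that makes itaconate, at 2.53 ± 0.32.

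Of 28 measured genes of the type I interferon response, 24 rose at 8 Gy and none fell (27 rose when adjusted over the list alone). Their median log2 fold change was 1.13 (camera, adjusted p = 1.11e-28, and adjusted p = 0.132 with an estimated correlation). Isg15, a ubiquitin-like modifier (mm10, chromosome 4, 156199455 to 156200796), rose from 11.8 ± 6.86 to 49.2 ± 11.5 CPM, the antiviral protein gene Rsad2 by 2.31 ± 0.29 and the RNA sensor gene Ifit1 by 2.21 ± 0.22 on the log2 scale. In the list for interferon gamma and antigen presentation, 14 of 26 rose and none fell, also when adjusted over the list alone, with a median of 0.89 (adjusted p = 2.47e-12, and adjusted p = 0.296 with an estimated correlation). Cd274, which encodes the PD-1 ligand PD-L1 (mm10, chromosome 19, 29367455 to 29388095), rose from 46.7 ± 15.8 to 94.5 ± 14.8 CPM, by 1.16 ± 0.13 on the log2 scale (adjusted p = 0.000287). The guanylate-binding protein gene Gbp5 rose by 1.79 ± 0.32, and Ido1, an enzyme of tryptophan breakdown, from 23.0 to 83.0 CPM, by 2.01 ± 0.40 on the log2 scale. Ifng itself stood at 2.78 ± 1.84 CPM at 0 Gy and 7.13 ± 3.80 CPM at 8 Gy (1.28 ± 0.43, adjusted p = 0.0474), and this call was lost in 12 of the 16 fits that left out 1 library, with GC-corrected values, with no filter, with a pseudocount of 1 and in the additive model.

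Among 30 p53 targets, 9 rose and 1 fell at 8 Gy (10 and 2 when adjusted over the list alone; camera, adjusted p = 2.03e-05, and adjusted p = 0.0268 with an estimated correlation). They included Ccng1 at 0.82 ± 0.11, Phlda3 at 0.69 ± 0.12 and the death receptor gene Eda2r at 1.05 ± 0.18. Trp53 itself had a log2 fold change of 0.11 ± 0.15 (adjusted p = 0.649). Of 26 genes of mitosis none passed the test alone, while 20 lay higher and 6 lower (camera, adjusted p = 0.00911, and adjusted p = 0.473 with an estimated correlation), a list call that ended with GC-corrected values. Of 24 DNA replication genes 2 rose (also 2 when adjusted over the list alone; adjusted p = 1.75e-05, and adjusted p = 0.323 with an estimated correlation). Mki67, a marker of cycling cells, stood at 271 ± 27.2 CPM at 0 Gy and 265 ± 43.0 CPM at 8 Gy (-0.05 ± 0.11, adjusted p = 0.770), a difference whose sign turned when the library medians were set equal.

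Genes of immunosuppressive myeloid cells were called in 5 of 16 cases, all higher (also 5 when adjusted over the list alone; adjusted p = 4.52e-05, and adjusted p = 0.0268 with an estimated correlation). Arg1, the arginase of suppressive macrophages, rose from 135 ± 61.3 to 446 ± 198 CPM, and the cytokine gene Il1b from 32.9 ± 9.59 to 103 ± 54.7 CPM. The list is not separate from others: Il1b and Ptgs2 are also in the inflammatory cytokine list, Ido1 in the interferon gamma list, and S100a8 and S100a9 in the neutrophil list. In the list of monocytes and macrophages 8 of 18 rose (9 when adjusted over the list alone; adjusted p = 8.77e-07, and adjusted p = 0.296 with an estimated correlation). Its leading members were the scavenger receptor gene Msr1 at 1.23 ± 0.17 and Ly6c2, a surface marker of inflammatory monocytes, at 1.33 ± 0.22. In the inflammatory cytokine list 7 of 21 rose and 1 fell (8 and 1 when adjusted over the list alone; adjusted p = 5.74e-06, and adjusted p = 0.286 with an estimated correlation), the fall being in Csf3, the growth factor of neutrophils, at -1.36 ± 0.27. Of 18 genes of cytotoxic T and NK cells, 7 rose (9 when adjusted over the list alone; adjusted p = 5.13e-07, and adjusted p = 0.296 with an estimated correlation). Gzmb, encoding granzyme B, rose from 16.9 ± 5.08 to 49.2 ± 20.1 CPM, a log2 fold change of 1.57 ± 0.26. None of 20 general T cell genes passed the test alone, also when adjusted over the list, but all 20 lay higher at 8 Gy, with a median of 0.29 (camera, adjusted p = 0.000126, and adjusted p = 0.473 with an estimated correlation). Pdcd1, encoding PD-1, stood at 36.5 ± 17.6 and 34.5 ± 10.6 CPM (adjusted p = 0.920), and the sign of its fold change turned with the scaling.

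Of 12 markers of alveolar type 1 cells, the flat gas-exchange epithelium, 8 fell at 8 Gy and none rose (9 when adjusted over the list alone; median -0.71, adjusted p = 0.000176, and adjusted p = 0.377 with an estimated correlation). Col4a3, a basement membrane collagen chain, fell by 2.38 ± 0.43 and Spock2 by 1.53 ± 0.27. Of 17 genes of fibroblasts and matrix, 10 fell (12 when adjusted over the list alone; adjusted p = 6.35e-05, and adjusted p = 0.296 with an estimated correlation). Eln, encoding elastin, fell by 2.14 ± 0.32 (from a mean of 225 to 56.7 CPM), and Mfap4, an elastic fibre protein, by 1.73 ± 0.36 on the log2 scale. Of 15 ciliated cell genes 6 fell (7 when adjusted over the list alone; adjusted p = 0.0270, and adjusted p = 0.615 with an estimated correlation), and outside that list the axonemal motor gene Dnah3 fell by 2.60 ± 0.55. Ccl21a, the chemokine of lymphatic vessels, which has near-identical copies in the mouse genome, fell from 12.1 ± 2.27 to 2.53 ± 1.52 CPM. Of 17 club cell genes 4 fell (6 when adjusted over the list alone; adjusted p = 0.0459, and adjusted p = 0.615 with an estimated correlation). Scgb1a1 (mm10, chromosome 19, 9083636 to 9087958, minus strand) stood at 2512 ± 1220 CPM at 0 Gy and 1411 ± 1380 CPM at 8 Gy and did not pass the test (adjusted p = 0.0589). Of 20 endothelial genes 4 fell (adjusted p = 0.0349, and adjusted p = 0.615 with an estimated correlation), and of 13 alveolar type 2 genes 2 fell (adjusted p = 0.179). The club cell and endothelial calls ended with GC-corrected values and without the 2 outlying libraries.

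In all, 3640 of 17546 genes passed the test at 8 Gy against 0 Gy, 822 higher and 2818 lower. Quantile normalization gave 1421 higher and 1764 lower, and setting the library medians equal gave 1568 and 1915, moving the median log2 fold change of all genes from -0.09 to 0.03 and 0.02. The count was 2309 without IgG 0 Gy replicate 1, 1983 without anti-PD-1 0 Gy replicate 2 and 2193 without anti-PD-1 8 Gy replicate 1. Beside these changes, 7 of 7 red blood cell genes rose (adjusted p = 1.26e-05, and adjusted p = 0.296 with an estimated correlation) and 9 of 12 mitochondrially encoded genes rose (10 when adjusted over the list alone; adjusted p = 5.13e-07, and adjusted p = 0.296 with an estimated correlation).

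**Figure D2:**
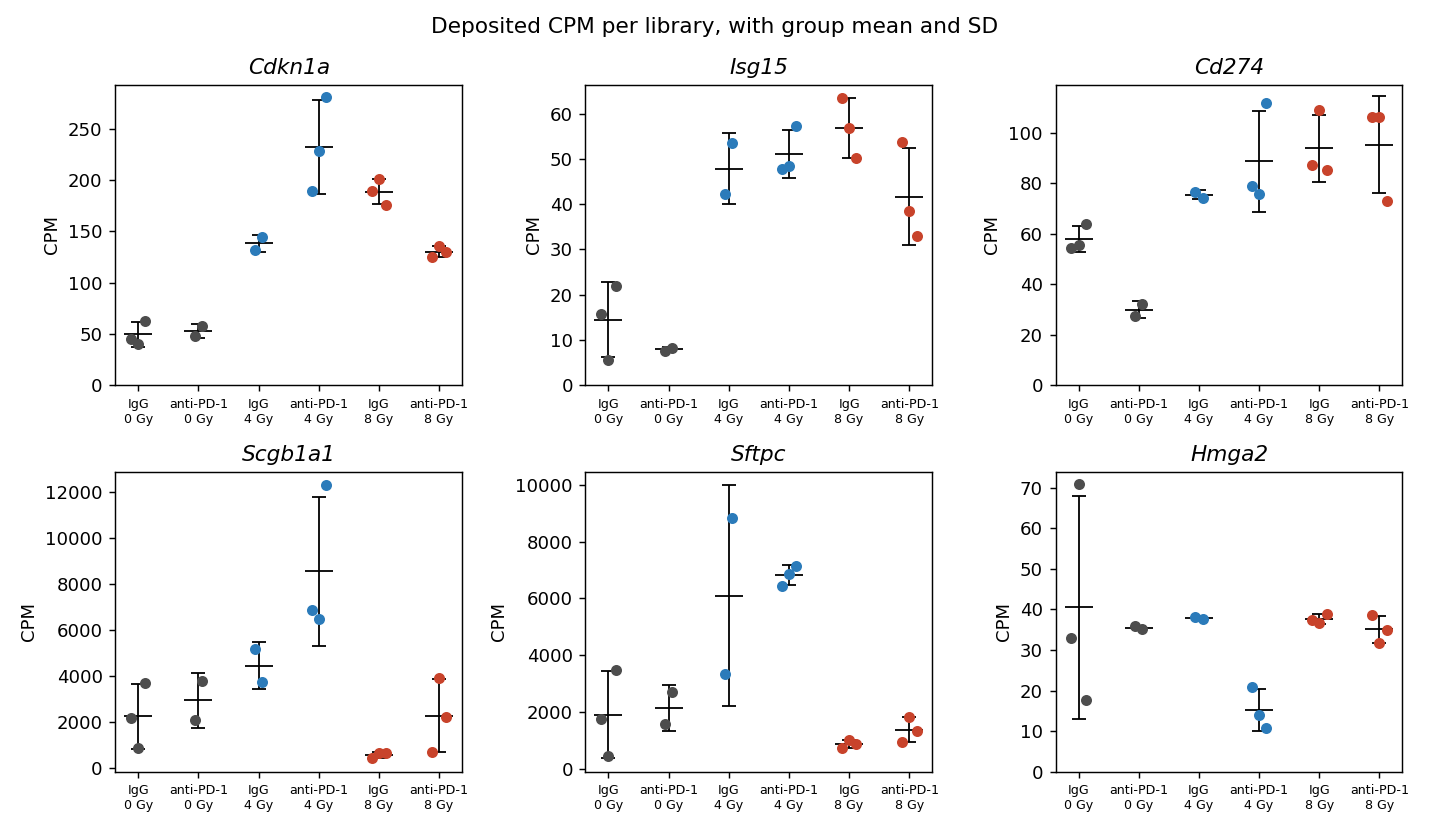
CPM of 6 genes in each library (points, y axes) by dose and antibody (x axes), with the mean and SD of each group. Grey, blue and red mark 0, 4 and 8 Gy. Cdkn1a lies at 40.5 to 62.8 CPM in the unirradiated libraries and at 125 to 201 CPM at 8 Gy. Taken over both antibodies, a mean that is not drawn, Scgb1a1 is highest at 4 Gy, at 6904 CPM.

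The lower dose was compared with unirradiated lungs in the same way (4 Gy n = 5, 0 Gy n = 5). Part of the p53 targets and most type I interferon genes were again higher. Here part of the markers of the lung epithelium and endothelium were also higher, while part of the genes of mitosis were lower. Cdkn1a stood at 195 ± 61.3 CPM at 4 Gy, a log2 fold change of 1.81 ± 0.13 (limma, adjusted p = 2.46e-05). Phlda3, a p53-induced inhibitor of Akt signalling, rose by 1.31 ± 0.13 and the stress cytokine gene Gdf15 by 1.90 ± 0.27. Of 30 p53 targets 11 rose and none fell (14 rose and 1 fell when adjusted over the list alone; camera, adjusted p = 1.11e-08, and adjusted p = 0.00772 with an estimated correlation).

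Of 28 type I interferon genes 25 rose at 4 Gy (also 25 when adjusted over the list alone; median 1.06, adjusted p = 2.20e-25, and adjusted p = 0.271 with an estimated correlation). Isg15 rose by 2.25 ± 0.27, Ifit3 by 2.13 ± 0.24 and Usp18, which removes Isg15 from its targets, by 1.54 ± 0.19. In the interferon gamma list 14 of 26 rose (16 when adjusted over the list alone; adjusted p = 2.17e-12, and adjusted p = 0.340 with an estimated correlation), with Cd274 at 83.3 ± 15.9 CPM, a log2 fold change of 0.96 ± 0.14 (adjusted p = 0.00358). Ifng (0.98 ± 0.45, adjusted p = 0.126) and Pdcd1 (-0.97 ± 0.34, adjusted p = 0.0582) did not pass. Of 26 mitosis genes 15 fell (19 when adjusted over the list alone; adjusted p = 1.13e-06, and adjusted p = 0.340 with an estimated correlation), and Mki67 stood at 189 ± 33.5 CPM (-0.52 ± 0.12, adjusted p = 0.0173).

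Club cell genes rose in 10 of 17 cases at 4 Gy and fell in 1 (14 and 1 when adjusted over the list alone; median 1.27, adjusted p = 2.11e-10, and adjusted p = 0.302 with an estimated correlation). Scgb3a2, a secretoglobin of the distal airways, rose from 77.0 ± 41.5 to 763 ± 291 CPM, by 3.23 ± 0.41 on the log2 scale (adjusted p = 0.00165), and the haptoglobin gene Hp by 2.01 ± 0.24. Scgb1a1 stood at 6904 ± 3260 CPM against 2512 ± 1220 CPM (1.38 ± 0.45, adjusted p = 0.0490), a call lost in 12 of the 16 fits that left out 1 library and under most other alternatives, quantile normalization and the fit without the outlying libraries among them. Of 13 alveolar type 2 genes 12 rose (also 12 when adjusted over the list alone; adjusted p = 2.17e-12, and adjusted p = 0.302 with an estimated correlation), and the surfactant gene Sftpb went from 406 ± 224 to 1836 ± 768 CPM. Of 12 alveolar type 1 genes 7 rose (10 when adjusted over the list alone; adjusted p = 1.11e-08, and adjusted p = 0.302 with an estimated correlation). Of 15 ciliated cell genes 8 rose (11 when adjusted over the list alone; adjusted p = 6.98e-09, and adjusted p = 0.343 with an estimated correlation), and of 20 endothelial genes 11 rose (also 11 when adjusted over the list alone; adjusted p = 2.69e-09, and adjusted p = 0.343 with an estimated correlation). Retnla, a macrophage gene of type 2 inflammation, rose by 2.41 ± 0.36. Beside these changes, the mean log2 level of the mitochondrially encoded genes was 10.342 to 10.872 at 4 Gy and 7.85 to 9.991 at 0 Gy. That of the red blood cell genes was 6.713 to 8.615 and 5.681 to 8.547. The calls of the lung markers Scgb3a2 and Hp held in every alternative run, whereas those of Sftpb and of Mki67 ended without the 2 outlying libraries of this dose, without IgG 4 Gy replicate 2 and when only these groups were fitted (that of Mki67 also without anti-PD-1 0 Gy replicate 2).

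In all, 3076 genes passed at 4 Gy, 935 higher and 2141 lower. The count was 130 when only the groups compared were fitted and 1474 in the additive model. Quantile normalization gave 1343 higher and 1061 lower, and equal medians gave 1275 and 798, moving the median of all genes from -0.14 to -0.05 and -0.03. Without the 2 outlying anti-PD-1 libraries 87 genes passed, 54 higher and 33 lower, all of them among the 3076, including Cdkn1a, Phlda3, Gdf15, Isg15, Ifit3, Cd274, Scgb3a2 and Hp. Leaving out 1 library gave 97 without IgG 4 Gy replicate 2, 1424 without IgG 4 Gy replicate 1, and 1620, 1588 and 5276 without IgG 0 Gy replicates 1, 2 and 3. It gave 1071 and 599 without anti-PD-1 0 Gy replicates 1 and 2, and 5748, 1502 and 988 without anti-PD-1 4 Gy replicates 1, 2 and 3.

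The doses were then compared with each other, which asks whether the response depended on the dose (8 Gy n = 6, 4 Gy n = 5). Nearly all markers of the lung epithelium and endothelium were lower at 8 Gy than at 4 Gy (74 of 77 in 5 lists), while most genes of mitosis and of checkpoints and regulatory T cells were higher. Scgb1a1 was lower by 2.58 ± 0.43 on the log2 scale (log2 fold change -2.58, limma, adjusted p = 0.00105), at 1411 against 6904 CPM. Ager, the leading alveolar type 1 gene, stood at 86.2 ± 61.9 CPM at 8 Gy and 572 ± 132 CPM at 4 Gy, and the surfactant gene Sftpc at 1116 ± 407 and 6534 ± 2010 CPM. Arg1 had the largest rise among the genes the naming rule admits, at 1.90 ± 0.28 (a mean of 446 against 115 CPM), and Il1b rose by 1.22 ± 0.17. Cdkn1a (-0.19 ± 0.13, adjusted p = 0.262), Cd274 (0.21 ± 0.13, adjusted p = 0.241) and Ifng (0.30 ± 0.43, adjusted p = 0.605) did not pass the test. For Cdkn1a this averages opposite differences in the arms. With IgG it stood at 132 and 144 CPM at 4 Gy and at 189, 201 and 176 CPM at 8 Gy. With anti-PD-1 it stood at 189, 228 and 281 CPM at 4 Gy and at 125, 136 and 130 CPM at 8 Gy.

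At 8 Gy against 4 Gy, 16 of 17 club cell genes fell (median -2.01, adjusted p = 4.83e-10, and adjusted p = 0.359 with an estimated correlation). So did 15 of 15 ciliated cell genes (adjusted p = 1.39e-09, and adjusted p = 0.371 with an estimated correlation) and 13 of 13 alveolar type 2 genes (adjusted p = 5.94e-10, and adjusted p = 0.359 with an estimated correlation). All 12 alveolar type 1 genes fell (adjusted p = 2.85e-10, and adjusted p = 0.359 with an estimated correlation), as did 18 of 20 endothelial genes (19 when adjusted over the list alone, with the other counts in these 5 lists the same; adjusted p = 1.39e-09, and adjusted p = 0.371 with an estimated correlation). Foxj1, the regulator of motile cilia, stood at 11.4 ± 8.86 CPM at 8 Gy and 67.4 ± 31.9 CPM at 4 Gy. Ccl21a had the lowest p of all genes, falling by 2.89 ± 0.22 (adjusted p = 3.31e-05). Rbpjl fell by 3.65 ± 0.37 and Matn4 by 2.87 ± 0.32, but these genes overlap on opposite strands and their reads may have been shared. Of the 74 lung markers called lower in these 5 lists, 65 were still called lower without the 2 outlying libraries. Hmga2, a chromatin protein of embryonic tissue and many carcinomas, stood at a mean of 24.3 CPM at 4 Gy and 36.4 CPM at 8 Gy (0.61 ± 0.26, adjusted p = 0.0843). With IgG its means were 37.9 CPM at 4 Gy and 37.7 CPM at 8 Gy, and with anti-PD-1 they were 15.2 and 35.1 CPM. In the list of alveolar macrophages, by contrast, 1 of 12 rose and 2 fell (adjusted p = 0.382).

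Of 26 mitosis genes 19 rose at 8 Gy against 4 Gy (also 19 when adjusted over the list alone; adjusted p = 1.84e-09, and adjusted p = 0.359 with an estimated correlation), among them the kinetochore motor gene Cenpe at 0.64 ± 0.10 and the spindle gene Tpx2 at 0.54 ± 0.08. The mean log2 level of the mitosis list was lowest in the 2 outlying libraries, at 5.355 and 5.01. With IgG it was 5.6 and 5.457 at 4 Gy and 5.84, 5.635 and 5.863 at 8 Gy, a small rise. Of 24 DNA replication genes 11 rose (12 when adjusted over the list alone; adjusted p = 3.36e-05, and adjusted p = 0.371 with an estimated correlation). Of 14 genes of checkpoints and regulatory T cells 10 rose (11 when adjusted over the list alone; adjusted p = 0.000318, and adjusted p = 0.371 with an estimated correlation), including the inhibitory receptor gene Tigit at 0.93 ± 0.20. Pdcd1 rose by 0.91 ± 0.32 (adjusted p = 0.0402), a call lost in 7 of the 16 fits without 1 library, with no filter and in the additive model. Of 16 immunosuppressive myeloid genes 6 rose (7 when adjusted over the list alone; adjusted p = 0.0146, and adjusted p = 0.359 with an estimated correlation). Fibroblast and matrix genes fell in 10 of 17 cases (also 10 when adjusted over the list alone; adjusted p = 0.00118, and adjusted p = 0.371 with an estimated correlation), smooth muscle genes in 6 of 8 (also 6 when adjusted over the list alone; adjusted p = 0.00380, and adjusted p = 0.371 with an estimated correlation). No interferon gamma list member passed, and 3 type I interferon genes rose and 2 fell (adjusted p = 0.319). In all, 6011 genes passed, 2988 higher and 3023 lower at 8 Gy. Without the 2 outlying libraries 2117 passed, 442 higher and 1675 lower, 2042 of them among the 6011. The count was 3566 without IgG 4 Gy replicate 1 and 3685 without IgG 4 Gy replicate 2.

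**Figure D3:**
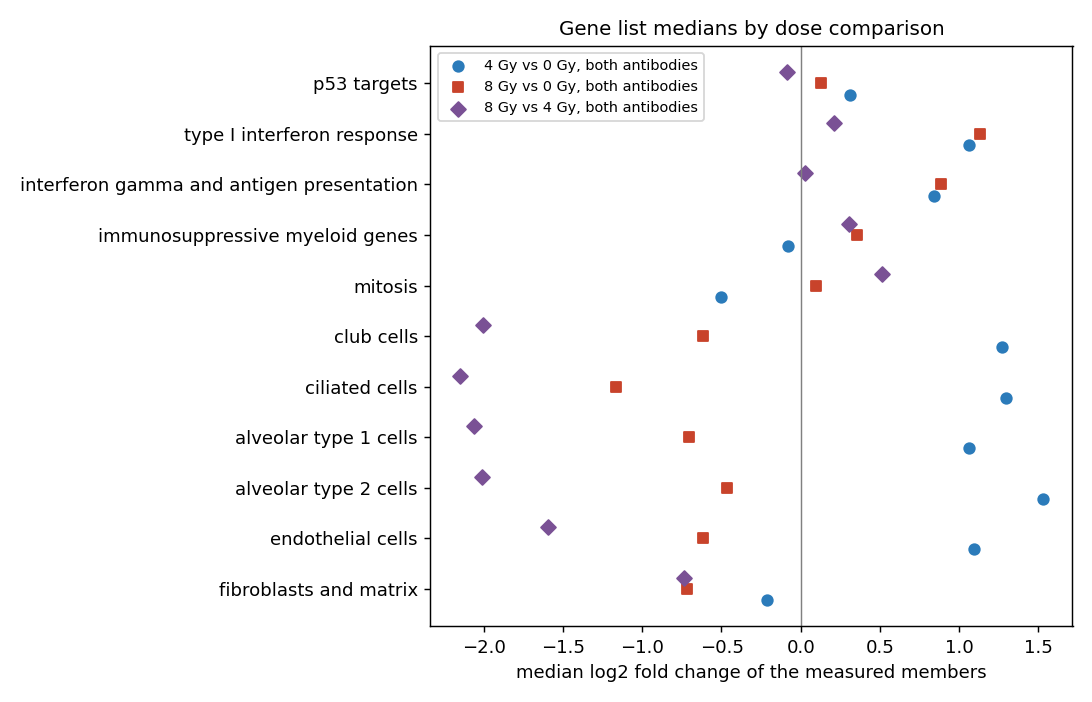
Median log2 fold change (x axis) of 11 gene lists (y axis) for 4 Gy against 0 Gy, 8 Gy against 0 Gy and 8 Gy against 4 Gy. The type I interferon list sits above 1 in both comparisons with 0 Gy (1.06 and 1.13), while the club cell list has a median of 1.27 at 4 Gy and -0.61 at 8 Gy.

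Anti-PD-1 was compared with IgG over all doses to ask what checkpoint blockade changed in the tissue (n = 8 and 8). Few genes passed, 12 of them lower with anti-PD-1. Ccl17, a chemokine of dendritic cells, stood at 20.4 ± 6.94 CPM with IgG and 9.68 ± 3.13 CPM with anti-PD-1 (-0.95 ± 0.17, limma, adjusted p = 0.0379). Itgax, encoding the integrin CD11c, stood at 332 ± 37.3 and 241 ± 64.7 CPM (-0.56 ± 0.10, adjusted p = 0.0374). Dcstamp, a macrophage fusion protein, fell by 1.20 ± 0.20, the secreted phospholipase gene Pla2g2d by 0.99 ± 0.15 and Il1rn, the interleukin-1 receptor antagonist, by 0.88 ± 0.17. Sphk1, which makes sphingosine-1-phosphate, was the largest rise at 1.32 ± 0.20, and Galnt15, a sugar transferase gene, rose by 1.11 ± 0.17. In all 41 genes passed, 29 higher and 12 lower, and the split was 27 and 25 with quantile normalization and 25 and 27 with equal medians. None passed in an additive model or without the 2 outlying libraries (limma, with 3353 genes at an unadjusted p under 0.05 in the fit as designed). None passed either without any 1 of IgG 0 Gy replicate 1, IgG 4 Gy replicates 1 and 2, IgG 8 Gy replicates 1 to 3, anti-PD-1 0 Gy replicates 1 and 2, anti-PD-1 4 Gy replicates 2 and 3, or anti-PD-1 8 Gy replicates 2 and 3. By contrast 1327 passed without IgG 0 Gy replicate 3, 920 without anti-PD-1 4 Gy replicate 1 and 472 without anti-PD-1 8 Gy replicate 1.

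No member of the lists of monocytes and macrophages (18 measured) or type I interferon (28) passed over all genes with anti-PD-1, and 6 and 2 were lower when adjusted over the list alone. Both lists lay lower as a whole (camera, adjusted p = 1.56e-07 and 9.47e-05, and adjusted p = 0.447 and 0.591 with an estimated correlation). The ciliated cell list lay higher, with 12 of 15 members higher when adjusted over the list alone and none over all genes (median 0.96, adjusted p = 4.76e-07, and adjusted p = 0.591 with an estimated correlation). The club cell list likewise had 10 of 17 higher when adjusted over the list alone (adjusted p = 0.000263, and adjusted p = 0.591 with an estimated correlation). The B cell list lay lower with no member past either adjustment (adjusted p = 0.000153, and adjusted p = 0.591 with an estimated correlation). Its mean log2 level was 5.966 in IgG 0 Gy replicate 3 and 5.349 in IgG 8 Gy replicate 2, and at most 4.42 in the others. At 4 Gy it was 3.925 and 3.539 with IgG and 4.42, 4.174 and 3.896 with anti-PD-1, so it did not lie lower at that dose. Scgb1a1 (1.07 ± 0.36, adjusted p = 0.131), Pdcd1 (0.48 ± 0.27, adjusted p = 0.338), Ifng (0.44 ± 0.36, adjusted p = 0.515) and Cd274 (-0.24 ± 0.11, adjusted p = 0.255) did not pass, nor did Cdkn1a, Mki67 or Trp53.

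Within the unirradiated lungs, part of the genes induced by glucocorticoid hormone were higher with anti-PD-1 than with IgG (n = 2 and 3). Zbtb16, a transcription factor induced by glucocorticoids, stood at 18.7 ± 5.42 CPM against 2.53 ± 1.76 CPM (log2 fold change 2.79 ± 0.40, limma, adjusted p = 0.0144), and Fkbp5, a chaperone of the glucocorticoid receptor, rose by 1.06 ± 0.16. Of 10 genes of that list 2 rose (6 when adjusted over the list alone; camera, adjusted p = 2.16e-08, and adjusted p = 0.0691 with an estimated correlation). The muscle genes Atp2a1 and Myl3 rose by 1.43 ± 0.20 and 1.76 ± 0.26, and Ptgir, the prostacyclin receptor gene, fell by 1.74 ± 0.23. In all 48 genes passed, 21 higher and 27 lower. None passed when only these groups were fitted, with 1878 at an unadjusted p under 0.05 in the fit as designed, and none without IgG 0 Gy replicate 1 or anti-PD-1 0 Gy replicate 2. The calls of Zbtb16 and Fkbp5 ended in each of these and without anti-PD-1 0 Gy replicate 1. The count was 7 without anti-PD-1 0 Gy replicate 1, 24 without either IgG 4 Gy library, 25 without IgG 8 Gy replicate 2 or anti-PD-1 8 Gy replicate 2, 31 without anti-PD-1 8 Gy replicate 1. It was 81, 84 and 95 without IgG 0 Gy replicate 2, anti-PD-1 4 Gy replicate 1 and IgG 0 Gy replicate 3.

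At 4 Gy, 2714 genes differed between the antibodies (n = 3 and 2), 1210 higher and 1504 lower with anti-PD-1. The endoplasmic reticulum chaperone gene Hspa5 fell by 1.34 ± 0.23 and the integrin gene Itgav by 0.99 ± 0.18, while Ccna1, a cyclin of the germ line, rose by 2.04 ± 0.33 (limma, adjusted p = 0.0300 for each). None passed without the 2 outlying libraries, which are 2 of the 3 anti-PD-1 libraries here, and none without any 1 of IgG 4 Gy replicates 1 and 2 or anti-PD-1 4 Gy replicates 2 and 3 (6457 at an unadjusted p under 0.05 in the fit as designed). The count was 1639 and 4179 without IgG 0 Gy replicates 1 and 2, 1205 without IgG 8 Gy replicate 2, 1362 without anti-PD-1 8 Gy replicate 2 and 5670 without anti-PD-1 4 Gy replicate 1.

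At 8 Gy (n = 3 and 3) a single gene differed between the antibodies, with 2185 at an unadjusted p under 0.05 in limma. It was D330041H03Rik, a long non-coding RNA gene outside the naming rule and chosen after its values were seen (mm10, chromosome 17, 24404649 to 24414542, minus strand). It stood at 4.99 ± 0.76 CPM with IgG and was higher with anti-PD-1 (2.43 ± 0.33, adjusted p = 0.0492). It overlaps the end of the surfactant lipid transporter gene Abca3 on the other strand (0.15 ± 0.12, adjusted p = 0.647), so the origin of its reads is uncertain. Scaling moved the median of all genes from 0.10 to -0.01 (quantile) and -0.02 (equal medians). No gene passed without any 1 of IgG 0 Gy replicate 1, IgG 8 Gy replicates 1 to 3, anti-PD-1 0 Gy replicates 1 and 2, anti-PD-1 4 Gy replicate 2, or anti-PD-1 8 Gy replicates 2 and 3. The count was 3 without IgG 0 Gy replicate 2 or 3, 2 without anti-PD-1 4 Gy replicate 3, 12 without anti-PD-1 4 Gy replicate 1 and 95 without anti-PD-1 8 Gy replicate 1. In each fit without 1 of the 2 IgG 4 Gy libraries, 1 other gene passed, which was lower with anti-PD-1, so the call of D330041H03Rik ended there too.

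Within each antibody arm, the response to 8 Gy was compared with the same arm's unirradiated lungs. With IgG (n = 3 and 3), Cdkn1a rose by 1.95 ± 0.17, Ccl24 by 3.12 ± 0.33 and Il1b by 2.10 ± 0.23, while the pericyte receptor gene Pdgfrb fell by 2.06 ± 0.25. Here 18 of 28 type I interferon genes rose (25 when adjusted over the list alone; camera, adjusted p = 4.51e-29, and adjusted p = 0.127 with an estimated correlation), and 3 of 16 immunosuppressive myeloid genes rose (also 3 when adjusted over the list alone; adjusted p = 1.05e-07, and adjusted p = 0.00397 with an estimated correlation). The p53 list had 4 higher and 1 lower of 30 (5 and 1 when adjusted over the list alone; adjusted p = 5.14e-05, and adjusted p = 0.0362 with an estimated correlation). With anti-PD-1 (n = 3 and 2), the interferon-induced GTPase gene Tgtp1 rose by 2.05 ± 0.22, Cd274 by 1.64 ± 0.20 and the glycolytic enzyme gene Hk2 by 1.03 ± 0.14. There 16 of 28 type I interferon genes rose (24 when adjusted over the list alone; adjusted p = 9.82e-27, and adjusted p = 0.143 with an estimated correlation). The counts were 1854 with IgG (253 higher, 1601 lower) and 497 with anti-PD-1 (168 higher, 329 lower). With IgG the split was 366 and 662 under quantile normalization and 459 and 781 with equal medians, which moved the median of all genes from -0.12 to 0.03 and 0.02.

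The fold changes of the arms at 8 Gy against 0 Gy, which share no library, had a Pearson r of 0.671 across 17546 genes (Spearman rho 0.678), and 75.0% of genes had the same sign. Genes are not independent replicates. Of the genes called, 270 passed in both arms, 99.3% of them with the same sign. At 4 Gy against 0 Gy the same r was 0.128 (rho -0.005), and it was -0.21 without IgG 0 Gy replicate 2. The IgG count at 8 Gy was 349, 430 and 479 without IgG 0 Gy replicate 1, IgG 8 Gy replicate 2 and IgG 8 Gy replicate 3, and 2904 without IgG 0 Gy replicate 2. The anti-PD-1 count was 14 and 165 without anti-PD-1 0 Gy replicates 2 and 1, 80 and 195 without anti-PD-1 8 Gy replicates 1 and 2. It was 322 without IgG 8 Gy replicate 2, and 779 and 892 without IgG 0 Gy replicates 2 and 3.

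At 4 Gy the arms gave very different counts. With IgG (n = 2 and 3) 1 gene passed, with 2016 at an unadjusted p under 0.05, and it was Cdkn1a (49.4 ± 11.8 CPM at 0 Gy and 138 ± 8.45 CPM at 4 Gy, limma, adjusted p = 0.0213). The call was lost when only these groups were fitted and without any 1 of IgG 0 Gy replicates 1 and 2, both IgG 4 Gy replicates, IgG 8 Gy replicates 1 and 2, anti-PD-1 4 Gy replicate 2 and anti-PD-1 8 Gy replicate 3. The count was 2 without IgG 4 Gy replicate 1, anti-PD-1 4 Gy replicate 1 or anti-PD-1 8 Gy replicate 2, 9 without anti-PD-1 8 Gy replicate 1 and 45 without IgG 0 Gy replicate 3. With anti-PD-1 (n = 3 and 2) 6894 genes passed, 2347 higher and 4547 lower. Cdkn1a rose by 2.12 ± 0.19 and Phlda3 by 1.89 ± 0.18, and Fkbp5 fell by 1.61 ± 0.16. Only 27 passed without the 2 outlying libraries, 1514 and 4083 without anti-PD-1 0 Gy replicates 2 and 1, and 3708 without anti-PD-1 4 Gy replicate 3. The split with anti-PD-1 was 3317 and 3664 under quantile normalization and 3441 and 3319 with equal medians, which moved the median of all genes from -0.13 to -0.01 and 0.03.

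Between 8 and 4 Gy, Il1b rose by 2.16 ± 0.26 with IgG (n = 3 and 2) and Fcna, a macrophage ficolin, by 2.14 ± 0.32. Ccl21a fell by 3.60 ± 0.32 and the alveolar genes Lpcat1 and Cldn18 by 1.48 ± 0.15 and 2.37 ± 0.26. In all 1330 genes passed, 288 higher and 1042 lower. Quantile normalization gave 447 and 847, equal medians 607 and 943, and GC-corrected values 674 and 1311. The count was 118 and 140 without IgG 4 Gy replicates 1 and 2. It was 550, 431 and 693 without IgG 8 Gy replicates 1, 2 and 3, and 2129 without IgG 0 Gy replicate 3. With anti-PD-1 (n = 3 and 3), 7340 genes passed, 4278 higher and 3062 lower. Equal medians gave 3566 and 3712 and quantile normalization 4014 and 3460. Among them the potassium channel gene Kcnk3 fell by 1.74 ± 0.18 and the mitotic gene Nusap1 rose by 1.16 ± 0.15. None passed without the 2 outlying libraries (limma, 9023 at an unadjusted p under 0.05 in the fit as designed), 3934 without anti-PD-1 4 Gy replicate 3 and 4490 without anti-PD-1 8 Gy replicate 1.

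Whether the dose response differed between the antibodies was tested by interaction terms. The joint test over both doses found 0 genes (limma, 4863 at an unadjusted p under 0.05), and the term at 8 Gy alone found 0 (598 at an unadjusted p under 0.05). The joint count was 3353 without anti-PD-1 4 Gy replicate 1, 3009 and 878 without IgG 0 Gy replicates 2 and 3, and 96 without IgG 8 Gy replicate 3. With all libraries it was 411 with quantile normalization, 82 with equal medians, 6772 with library weights and at most 1 under the other alternatives. The term at 4 Gy alone, tested after the data were seen, found 1593 genes, 660 higher and 933 lower in the anti-PD-1 arm's response (equal medians gave 1012 and 907). Its leading genes were Tifab at 1.78 ± 0.29 and Pik3r5, a regulatory subunit of an immune cell lipid kinase, at 1.32 ± 0.21, and Osmr, the oncostatin M receptor gene, at -1.68 ± 0.27 (adjusted p = 0.0334 for each). None passed without the 2 outlying libraries or with GC-corrected values (limma, 5945 at an unadjusted p under 0.05 in the fit as designed). None passed without any 1 of IgG 0 Gy replicates 1 and 3, IgG 4 Gy replicates 1 and 2, IgG 8 Gy replicate 2, anti-PD-1 0 Gy replicate 2, anti-PD-1 4 Gy replicates 2 and 3, or anti-PD-1 8 Gy replicate 2. The count was 3, 55, 150 and 877 without anti-PD-1 0 Gy replicate 1, anti-PD-1 8 Gy replicates 1 and 3 and IgG 8 Gy replicate 1. It was 4809 and 4719 without IgG 0 Gy replicate 2 and anti-PD-1 4 Gy replicate 1.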

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

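The tests of a tumour share, of scaling to library totals, and of the added sequences CREERT2 and RFP were chosen after the results they bear on were seen, as were the interaction at 4 Gy and the fits without the outlying libraries, with totals free of mitochondrial and haemoglobin genes, with GC-corrected values and with equal medians. The rule that reads correlations across libraries was made stricter after their values were seen.

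The change from 0 to 4 Gy differed between the antibodies for 1593 genes in the single-term interaction test, a difference between groups that the joint test of both doses did not find (0 genes in limma, 4863 at an unadjusted p under 0.05). It was 0 without both outlying anti-PD-1 4 Gy libraries, and also without either alone.

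The lowest CPM of the CREERT2 sequence in any library was 6.80 (highest 34.7), and that of RFP was 6.93 (highest 23.1), far above the floor of 3 reads, at most 0.125 CPM. These sequences carry no mouse chromosome in the deposited values and belong to no gene list, and GFP, entered likewise, stood at 0.0173 to 0.151 CPM. With group means removed, CREERT2 correlated with Hmga2, the marker used for tumour content, at r = 0.762 over 16 libraries (permutation p = 0.0713, rho = 0.582 with p = 0.0989, adjusted p = 0.112 over 4 relations, r = 0.515 without the 2 libraries farthest from the median). RFP had r = 0.409 (permutation p = 0.316, rho = 0.206 with p = 0.571, adjusted p = 0.316, r = -0.00145 without the 2 farthest). Whether the tumour cells carry either sequence cannot be told apart from another origin, because neither relation passed, and no other origin was tested.

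Epithelial and endothelial markers were lower at 8 Gy than at 4 Gy (74 of 77 measured genes of 5 cell types), a difference that could come from the outlying libraries, from a different tumour share, or from the dose. The outlying libraries alone are argued against, since 87.8% of the called markers (65 of 74) stayed lower without both. If a different share of tumour tissue lowered markers of all normal cells alike, which was not tested, alveolar macrophage markers would fall too. Their median (-0.18) lay 1.93 log2 units above the epithelial median (-2.11), with an SE of 0.156 from resampling genes, not libraries. With IgG that list's mean log2 level was 5.361 and 5.303 at 4 Gy and 5.655, 5.732 and 5.605 at 8 Gy. In this arm that argues against tumour share as the whole cause. With anti-PD-1 the list's mean was 5.939, 5.602 and 5.942 at 4 Gy and 5.28, 5.253 and 5.159 at 8 Gy, a fall that leaves the question open there. A part played by tumour share cannot be told apart. Hmga2 correlated with the epithelial mean at r = -0.753 over 16 libraries (group means removed, permutation p = 0.00767, rho = -0.759 with p = 0.01002, adjusted p = 0.0307 over 4 relations). However, r was -0.416 without the 2 libraries farthest from the median, short of the -0.5 asked for. The means of Hmga2 at 4 and 8 Gy were 15.2 and 35.1 CPM with anti-PD-1 but 37.9 and 37.7 CPM with IgG. An effect of dose on these cells stays open as a hypothesis.

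More genes were lower than higher at 8 Gy against 0 Gy (77.4% of the calls), which could come from a few abundant transcripts, from GC content, from the scaling to library totals or from the dose. Taking mitochondrial and haemoglobin genes out of the totals left 75.5% lower, and GC-corrected values left 73.4%, which argues against both as the whole cause. With library medians set equal the share was 55.0%, so the excess of lower calls may come from the scaling, although such centring itself pulls the split towards an even one. A true excess of lower genes stays open, since these data hold no external standard.

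Other splits of the same libraries bear on whether chance can give the counts. For 8 Gy against 0 Gy (3640 genes) 1 of 100 splits, the real one, gave as many, and the highest other gave 1616. Chance is thus an unlikely source of the count. However, only 100 of 200 possible splits were run, and 1 of 100 is the smallest share these can give, so it is not excluded. For 8 Gy against 4 Gy (6011 genes) it was likewise 1 of 100, with 3500 the highest other, and the same holds. For 4 Gy against 0 Gy (3076 genes) 7 of 100 gave as many, up to 6105, and for anti-PD-1 against IgG (41 genes) 7 of 100 did, up to 3393. There such counts are not rare among the splits, so chance stays open. At 4 Gy, some of the other splits with as many genes kept the anti-PD-1 libraries at their real doses. The rest of them set the 2 outlying libraries as that arm's 0 Gy group. Splits that did neither gave at most 1 gene, so the 7 of 100 does not measure chance alone. For anti-PD-1 against IgG, what gave the large counts was not tested. For 8 Gy against 0 Gy with IgG (1854 genes), 8 Gy against 4 Gy with anti-PD-1 (7340) and anti-PD-1 against IgG at 8 Gy (1), the highest of the other splits gave 0 in each, and 10 splits (the real one 1 of them) are too few for a share under 0.05.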

How the results depend on the processing

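The fits without both outlying libraries, with library weights, with totals free of mitochondrial and haemoglobin genes, with GC-corrected values, with equal medians, and the single-term interactions were tests chosen after the data were seen. Of 480 named gene results, 220 kept their direction and side of the threshold under every alternative run, and 248 under every one except left-out replicates. Of 161 list results 5 did, since an estimated correlation ended the others. At 8 Gy against 0 Gy over both antibodies, Cdkn1a, Cd274 and the 6 type I interferon genes named by the rule (Isg15, Ifit1, Ifit3, Rsad2, Ifi44 and Xaf1) were kept under every alternative run. Named gene results that lost their call numbered 176 without both outlying libraries, 103 with only the groups compared, 85 in the additive model, 36 with GC-corrected values, 34 with quantile normalization, 32 with no filter, 23 with equal medians, 19 with totals free of mitochondrial and haemoglobin genes, 10 with a pseudocount of 0.1, 1 with a pseudocount of 1 and 2 with weights. Results that gained one numbered 5 with weights, 1 with quantile normalization and 1 with GC-corrected values. The cause of the changes below was not tested, except that fits with fewer libraries or groups have fewer degrees of freedom. Depth limits genes near the floor of 3 reads, which lies highest in anti-PD-1 4 Gy replicate 2, at 0.125 CPM, and next in anti-PD-1 0 Gy replicate 1, at 0.1002 CPM.

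The replicate numbers gave no sign of pairing the libraries: of 36 pairs with the same number, 11 had deviations correlated above 0.1 (from -0.546 to 0.442, median -0.101, against 0.0165 for different numbers), and 3 of 16 libraries correlated best with their own number. In a group of 2 libraries the deviations from the group mean are exact opposites. These correlations are therefore not independent and cannot exclude pairing. A replicate block ended 62 named gene calls and began 1. It gave 9 genes for anti-PD-1 against IgG over all doses (41 without it), 30 at 0 Gy (48), 0 at 4 Gy (2714), 306 for 8 Gy against 0 Gy with anti-PD-1 (497), and 1 each for the joint interaction (0), the interaction at 8 Gy (0) and that at 4 Gy (1593). The other counts stayed within 1.5 times.

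Without both outlying libraries the counts were 87 for 4 Gy against 0 Gy, 2117 for 8 Gy against 4 Gy, 0 for anti-PD-1 against IgG over all doses, 3 for 4 Gy against 0 Gy with IgG, 27 for the same with anti-PD-1, 0 for 8 Gy against 4 Gy with anti-PD-1, and 0 for anti-PD-1 against IgG at 4 Gy, at 8 Gy and in the interaction at 4 Gy. These zeros are from limma, and the counts at an unadjusted p under 0.05 with all libraries were 3353, 9023, 6457, 2185 and 5945.

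Library weights raised every count, to the following where by over 1.5 times: 7317 for 8 Gy and 7029 for 4 Gy against 0 Gy, 9164 for 8 Gy against 4 Gy, 2808 for anti-PD-1 against IgG, with IgG 8158, 1537 and 4549 for the same order of doses, 1509 for 8 Gy against 0 Gy with anti-PD-1, 509, 7221 and 2195 for the antibodies at 0, 4 and 8 Gy, and 6772, 59 and 6708 for the joint interaction and those at 8 and 4 Gy. The weights ran from 0.306 to 4.66.

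Fitting only the groups compared gave 130 for 4 Gy against 0 Gy, 476 and 0 for 8 and 4 Gy against 0 Gy with IgG, 3218 for 8 Gy against 4 Gy with IgG, 131 for 8 Gy against 0 Gy with anti-PD-1, and 0, 1581 and 28 for the antibodies at 0, 4 and 8 Gy. The additive model gave 1474 for 4 Gy against 0 Gy and 0 for anti-PD-1 against IgG. Quantile normalization gave 1028 and 30 for 8 and 4 Gy against 0 Gy with IgG, 8 for the antibodies at 8 Gy, and 411 and 2591 for the joint interaction and that at 4 Gy. Equal medians gave 19 for 4 Gy against 0 Gy with IgG, 13 for the antibodies at 8 Gy and 82 for the joint interaction. GC-corrected values gave 326 for anti-PD-1 against IgG, 4 for 4 Gy against 0 Gy with IgG, 927 for 8 Gy against 0 Gy with anti-PD-1, 1205 and 10 for the antibodies at 4 and 8 Gy, and 0 for the interaction at 4 Gy. No filter on low values gave 97, 1506 and 0 for the antibodies at 0, 4 and 8 Gy, and 1, 6 and 414 for the joint interaction and those at 8 and 4 Gy. Totals without mitochondrial and haemoglobin genes gave 30 and 0 for the antibodies at 0 and 8 Gy. A pseudocount of 1 gave 2 for 4 Gy against 0 Gy with IgG and 6 for the antibodies at 8 Gy, and one of 0.1 moved no count by over 1.5 times.

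With each replicate left out in turn, the counts ran from 1983 to 4407 for 8 Gy against 0 Gy, 97 to 5748 for 4 Gy against 0 Gy, 3566 to 7406 for 8 Gy against 4 Gy and 0 to 1327 for anti-PD-1 against IgG. With IgG they ran from 349 to 2904 (8 against 0 Gy), 0 to 45 (4 against 0 Gy) and 118 to 2129 (8 against 4 Gy), and with anti-PD-1 from 14 to 892, 1514 to 8032 and 3934 to 8404. For the antibodies they ran from 0 to 95 at 0 Gy, 0 to 5670 at 4 Gy and 0 to 95 at 8 Gy, for the joint interaction from 0 to 3353, and for those at 8 and 4 Gy from 0 to 2 and 0 to 4809. Where this leaves a group with 1 library, that library is assumed to vary like the other groups.

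The correlation of fold changes between the arms at 8 Gy against 0 Gy was 0.731 over genes past the threshold in either arm, 0.730 over the upper part by mean expression, and 0.526 to 0.726 with a replicate left out. At 4 Gy against 0 Gy it ran from -0.210 (without IgG 0 Gy replicate 2) to 0.401. Signs turned for genes that did not pass the test: Mki67 at 8 Gy against 0 Gy with equal medians (0.0536), Pdcd1 in that comparison with quantile normalization (0.0239), equal medians (0.0521), weights (0.125) and GC-corrected values (0.00719) and from -0.418 to 0.308 with a replicate left out, Trp53 at 8 Gy against 4 Gy with GC-corrected values (0.00935), and Ifng there, from -0.00447 (without anti-PD-1 4 Gy replicate 1) to 0.617 with a replicate left out. With a replicate left out, the median of the interferon gamma list for the antibodies at 0 Gy ran from -0.567 to 0.0544 (without anti-PD-1 0 Gy replicate 2), and that of the cytotoxic list at 8 Gy from -0.283 to 0.208 (without anti-PD-1 8 Gy replicate 3).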

Other observations

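The tests of the muscle genes below were chosen before their results were seen, but the rule that reads the myosin ratio and the correlations was made stricter afterwards. The fits with GC-corrected values and without the outlying libraries were tests chosen after the data were seen.

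Part of the genes induced by low oxygen were higher at 8 Gy than at 0 Gy. Of 14 measured hypoxia genes 6 rose and 1 fell (8 and 1 when adjusted over the list alone; camera, adjusted p = 3.42e-05, and adjusted p = 0.206 with an estimated correlation). Hk2, the hexokinase of glycolytic tissue, stood at 61.6 ± 11.2 CPM at 0 Gy, 72.1 ± 7.01 CPM at 4 Gy and 110 ± 13.4 CPM at 8 Gy (0.89 ± 0.09 at 8 Gy, limma, adjusted p = 0.000149), and Ldha, the lactate dehydrogenase chain of muscle and tumours, rose by 0.56 ± 0.10. Against 4 Gy, 8 hypoxia genes rose and 2 fell (also 8 and 2 when adjusted over the list alone; adjusted p = 0.0105, and adjusted p = 0.371 with an estimated correlation), with the prolyl hydroxylase gene Egln3 up by 1.32 ± 0.24 and Vegfa, the vessel growth factor, at -1.38 ± 0.26.

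Part of the circadian genes were lower at 8 Gy. Of 13 clock genes 4 fell against 0 Gy (also 4 when adjusted over the list alone; adjusted p = 0.0270, and adjusted p = 0.452 with an estimated correlation), a list call that ended without IgG 0 Gy replicate 3, IgG 8 Gy replicate 1 or anti-PD-1 0 Gy replicate 2. Per3 stood at 37.5 ± 14.3 CPM at 4 Gy and 10.6 ± 5.07 CPM at 8 Gy (-1.75 ± 0.29, adjusted p = 0.00113). Against 4 Gy, 7 fell and 2 rose (also 7 and 2 when adjusted over the list alone; adjusted p = 0.0395, and adjusted p = 0.522 with an estimated correlation), a call that ended without IgG 4 Gy replicate 1, IgG 8 Gy replicate 1 or anti-PD-1 8 Gy replicate 3. The labels give no hour of harvest. Over both antibodies, part of the glucocorticoid-induced genes fell at both doses against 0 Gy, 4 of 10 at 8 Gy (also 4 when adjusted over the list alone; adjusted p = 0.0394, and adjusted p = 0.377 with an estimated correlation) and 6 of 10 at 4 Gy (7 when adjusted over the list alone; adjusted p = 0.00372, and adjusted p = 0.302 with an estimated correlation). The call at 8 Gy ended with GC-corrected values, without the outlying libraries and without any 1 of IgG 0 Gy replicate 2, IgG 8 Gy replicate 1, anti-PD-1 0 Gy replicate 2, anti-PD-1 4 Gy replicates 1 and 3 and anti-PD-1 8 Gy replicate 2. Within the arms at 8 Gy against 0 Gy, with IgG no member passed over all genes or over the list alone (limma, with 4753 of all genes at an unadjusted p under 0.05; median -0.02, camera, adjusted p = 0.2504), and with anti-PD-1 4 fell (7 when adjusted over the list alone; adjusted p = 2.11e-05, and adjusted p = 0.143 with an estimated correlation). No gene passed the interaction at 8 Gy (limma, 598 at an unadjusted p under 0.05), so a difference between the arms was not found gene by gene. The mean log2 level of the list was 4.83, 5.34 and 4.78 with IgG at 0 Gy and 5.05, 4.98 and 4.97 at 8 Gy, and with anti-PD-1 it was 5.88 and 6.10 at 0 Gy and 4.86, 4.86 and 5.16 at 8 Gy. Fkbp5 stood at 113 ± 21.7 CPM at 0 Gy, 85.8 ± 13.8 CPM at 4 Gy and 99.1 ± 8.98 CPM at 8 Gy with IgG and did not pass in either comparison (adjusted p = 0.384 and 0.458). With anti-PD-1 it was 235 ± 28.3 CPM at 0 Gy, 76.3 ± 4.10 CPM at 4 Gy and 105 ± 10.1 CPM at 8 Gy, so its difference over both arms lies mostly in the high level of the 2 anti-PD-1 libraries at 0 Gy. Plasma cell genes had 1 of 11 lower at 8 Gy and 2 of 11 at 4 Gy (3 at each dose when adjusted over the list alone; adjusted p = 0.0602 and 0.440), with Ighg1, an immunoglobulin heavy chain, at 37.1 ± 29.3, 5.33 ± 3.56 and 7.97 ± 4.36 CPM. The call of Ighg1 ended without anti-PD-1 0 Gy replicate 1 at 8 Gy. At 4 Gy it ended without IgG 4 Gy replicate 2, without the outlying libraries and when only the groups compared were fitted.

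Part of the genes of cardiac and skeletal muscle were lower at 8 Gy than at 0 Gy, with 4 of 13 falling (also 4 when adjusted over the list alone; camera, adjusted p = 0.00414, and adjusted p = 0.446 with an estimated correlation), whereas at 4 Gy 3 rose and 3 fell (5 and 3 when adjusted over the list alone; adjusted p = 0.197). Acta1, the actin of skeletal muscle, stood at 6.36 ± 5.85 CPM at 0 Gy, 0.697 ± 0.970 at 4 Gy and 0.218 ± 0.113 at 8 Gy. In the unirradiated libraries it was 2.25, 1.37 and 2.67 CPM with IgG and 12.8 and 12.7 CPM with anti-PD-1, and Ckm and Tnnt3 were highest in the same 2 libraries (7.93 and 6.73 CPM, and 7.25 and 9.11 CPM). One hypothesis was that adult skeletal muscle was carried along with the unirradiated lungs. Adult muscle would hold little Myh8, the perinatal myosin, yet the median ratio of Myh8 to the adult myosins Myh1, Myh2 and Myh4 together was 4.08 in these 5 libraries (SD 2.23, from 0.234 to 6.04, above 2 in 4 of them), a spread too wide to decide. A muscle programme of the tumour cells, the other hypothesis, cannot be told apart either. The 4 called muscle genes had r = -0.594 with Hmga2 over 16 libraries (group means removed, permutation p = 0.0841, rho = -0.647 with p = 0.0447, adjusted p = 0.112 over 4 relations, r = -0.711 without the 2 libraries farthest from the median), which did not pass. These genes are few, and Acta1, Ckm and Tnnt3 were low in the irradiated libraries except anti-PD-1 4 Gy replicate 2. There they stood at 2.36, 2.71 and 2.17 CPM, near the unirradiated IgG libraries, where Ckm was 1.17, 0.647 and 1.76 CPM. Muscle transcripts were thus not confined to unirradiated lungs. A relation within groups also says little of a difference between groups. None of the 13 muscle genes is in another list.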
